A study of Mus musculus with 4 samples.

How the data were processed

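The data are RNA sequencing counts of colonic epithelial cells from mice given dextran sulfate sodium, with 2 WT libraries and 2 libraries from mice without epithelial Smad4. Per the labels' protocols, the mice were 8 to 10 weeks old, total RNA was extracted with TRIZOL, libraries were made from 1.5 µg of total RNA with random hexamer primers, and the products were circularized. Whether the libraries keep strand is not given in the sources used here, so a gene and an antisense partner cannot be told apart. The authors deposited a table of whole-number counts per gene, not normalized, for 31227 Ensembl gene IDs and 4 libraries. Per the submitters' processing notes, the tools were FastQC (version given as 0.19.7), HISAT2 2.1.0, SAMtools 1.9 and StringTie 1.3.3b and the build was GRCm38 (mm10). The notes as given do not say which tool made the counts, and the annotation release, the read length and the treatment of reads that match several genes are not given in the sources used here.

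Each column was matched to a library by its title, and 0 columns were left over. Gene symbols and positions came from GENCODE M21 on GRCm38, which named 31207 of the IDs; the other 20 held at most 0.00197% of a library's counts. A symbol shared by several rows (39 symbols, 80 rows) was kept as separate entries. Genes whose models overlap or resemble each other are uncertain, since the counting could have moved reads between them.

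Of 19618 genes with any count, edgeR's filterByExpr kept 15838. Counts were normalized by TMM and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test (glmQLFit and glmQLFTest) with genotype as the only term, and p-values were adjusted over the tested genes by Benjamini and Hochberg with a threshold of 0.05. A change is KO relative to WT. Levels are CPM from TMM-scaled library sizes. The SE of a log2 fold change is its size divided by the square root of its F statistic. Where a genotype had no count in either library, the fold is a lower bound from a floor of 3 counts over the group, which is 0.0299 CPM for WT and 0.0237 CPM for KO. Floors cover counting error only, since PCR copies are not independent molecules. The biological coefficient of variation was 0.196.

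Before the data were examined, 33 gene lists for pathways, epithelial cell types and other cell types were fixed, along with the tests, the alternatives and a rule for the genes named. The 30 lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 30 lists. With the correlation estimated from the data no list passed. With 2 libraries per group this estimate, and the test that uses it, rest on very few residuals. All 15 lists that passed with the preset lost their calls, so this loss does not tell them apart. Of the lists passing with the preset, the antimicrobial (0.249), TGF-β ligand and receptor (0.127), epithelial-mesenchymal (0.0830) and posterior Hox (0.0639) lists had estimates above 0.01. The others had lower estimates, such as -0.0862 for neutrophil markers. A higher correlation thus cannot account for the calls these others lost. By fry, which asks whether a list's genes move 1 way on balance, 18 lists passed. By its mixed test of any change 27 did. Neither compares a list with other genes.

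The rule for named genes took Smad4, Yap1, Wwtr1 and the 3 TGF-β ligands. It also took the 10 risen and the 10 fallen genes with the largest log2 fold change among those with adjusted p under 0.05, non-overlapping libraries and a mean of at least 5 CPM, leaving out unnamed gene models, pseudogenes, mitochondrial and immunoglobulin genes. From each list it took the up to 4 members with the smallest p, and from each list of other cell types the member with the highest level. It gave 152 distinct tested genes, of which 110 passed; the others are summarised through their lists. Of the genes the rule took, 1 is not reported here. Any gene outside the rule is said to have been chosen after its values were seen.

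The fit was tested on simulated data. Counts were drawn for the real genes from the real means, dispersions and library sizes, with 200 genes changed by 1.5, 2 or 4-fold. The test recovered 8.36%, 51.0% and 78.2% of them in a mean of 5 runs of Smad4 KO against WT with about 15400 genes tested, and 17.3% of its calls were false. With 2400 genes changed (3 runs, about 15390 genes tested) it recovered 34.9%, 65.5% and 81.7%, and 5.14% of calls were false.

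Alternatives were DESeq2 size factors, upper-quartile normalization and library totals in place of TMM; no low-count filter and a filter of 1 CPM in 2 libraries; DESeq2 1.42.0 (Wald test), limma-voom, edgeR's likelihood ratio test and its robust quasi-likelihood fit; a 2-fold minimum; annotated genes only; leaving out the 20 most abundant genes; and leaving out each library in turn. Whole-library checks used log2(CPM + 1). Libraries of a genotype were compared for duplication by chi-square over genes with at least 100 counts in the pair.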

Results

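RNA sequencing measured gene expression in colonic epithelial cells of mice with experimental colitis. The mice had drunk water with 3.5% dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium, for 5 days and plain water after that until they were killed on day 7. The labels give the time as 5 days. A group of 2 wild-type (WT) libraries (replicates 1 and 3) was compared with a group of 2 libraries from mice that lack Smad4 in the epithelium (Smad4 KO, replicates 1 and 2). No library from mice without DSS was analysed here, so the comparison shows how the genotypes differed under DSS and not what DSS did. The WT libraries held 56018009 and 42577920 counts and the KO libraries 61260099 and 67927291. Levels are given as CPM, counts scaled to a common library size, as mean ± SD over the 2 libraries of a genotype. At these depths a count of 1 in a library stood for 0.0150 to 0.0229 CPM. The labels do not say whether libraries of a genotype came from separate mice, so the p-values measure only the spread between these libraries, which may be technical.

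Smad4 is the shared partner of the receptor-activated Smad proteins that carry TGF-β and BMP signals to the nucleus. Its gene (ENSMUSG00000024515) lies on the minus strand of chromosome 18, from 73639009 to 73703780 in GENCODE M21 on GRCm38. Its level was 166 ± 19.4 CPM in WT and 46.3 ± 7.34 CPM in KO, with 152 and 180 CPM in the WT libraries and 51.5 and 41.1 CPM in the KO libraries. It fell 3.59-fold (log2 fold change -1.84, SE 0.143, edgeR adjusted p = 0.00163), and its direction went with the labels in 4 of 4 libraries.

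The 2 genotypes differed in 2412 of 15838 tested genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 1398 rose in the KO libraries and 1014 fell. A change of at least 2-fold was seen in 697 of the risen and 404 of the fallen genes. Among the genes that rose most were St3gal4, a sialyltransferase (3.79 ± 0.230 to 101 ± 0.428 CPM, 26.6-fold), Samd5 (22.3-fold), the plasminogen activator Plat (18.7-fold), the neutrophil-attracting chemokine Cxcl5 (2.70 ± 0.515 to 44.9 ± 1.34 CPM, 16.5-fold) and the iron-binding protein lactoferrin, Ltf (10.9 ± 0.275 to 170.0 ± 3.30 CPM, 15.6-fold). The orphan receptor Gpr27 (16.7-fold), the interleukin 5 receptor chain Il5ra (14.8-fold) and Ly6d (14.4-fold) rose as well. The largest falls were in Mettl7a2, which had 10.6 ± 1.17 CPM in WT and no count in either KO library and so was at least 447-fold lower (floor of 3 counts over the group), and its neighbour in sequence Mettl7a3 (means of 10.3 and 0.0300 CPM). The mucosal pentraxin Mptx1 fell from 430 ± 30.0 to 1.81 ± 0.625 CPM. The sugar phosphate transporter Slc37a2 fell from 225 ± 1.24 to 2.58 ± 0.212 CPM. Gsdmc (38.2-fold), AI854703 (34.2-fold), Cyp2f2 (24.5-fold) and Ephb6 (23.3-fold) also fell. The edgeR adjusted p of these genes lay between 4.92e-05 for St3gal4, Ltf and Slc37a2 and 0.00265 for Il5ra. The log2 fold change of Il5ra was 3.89, and 4.5 without WT replicate 1. That of Mettl7a3 was -8.25, and -7.36 without KO replicate 1, which had no count of it. Without KO replicate 2 no count was left in KO, and Mettl7a3 was at least 206-fold lower (floor of 3 counts). Mettl7a2, Mettl7a3, Gsdmc and Mptx1 belong to families of similar genes between which the counting could have split reads, so their values are uncertain. An entry for Sept2 (ENSMUSG00000116048) had 0 CPM in WT and 111 ± 2.46 CPM in KO. With its counts added to those of the other Sept2 entry, which overlaps it, the gene had 123 to 140 CPM in the 4 libraries and its change did not pass (log2 fold change -0.10, edgeR adjusted p = 0.422).

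**Figure D1:**
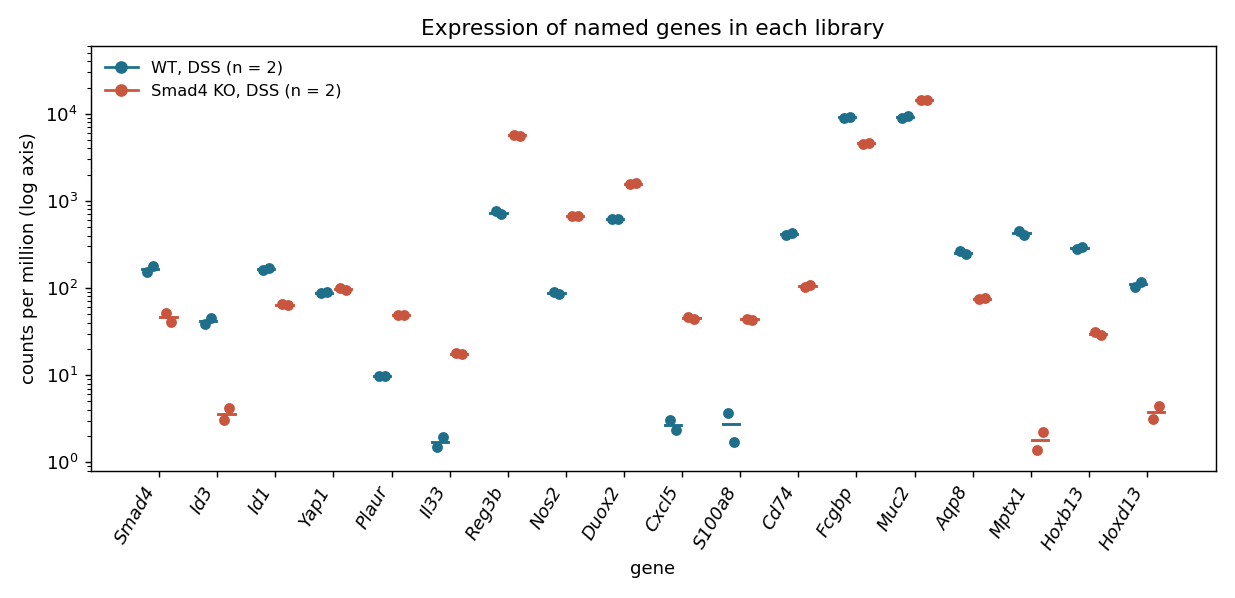
Level in CPM (vertical log axis) of 18 named genes (horizontal axis) in each library. Each point is 1 library, each bar the mean of a genotype, with the 2 WT libraries in blue and the 2 Smad4 KO libraries in red; for Smad4 the KO libraries, at 51.5 and 41.1 CPM, lie below the WT libraries, at 152 and 180 CPM.

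The libraries split by genotype. The first principal component of log2(CPM + 1) took 74.9% of the variance and separated the genotypes. Across genes, which are not independent replicates, Pearson's r was 0.991 for the WT pair and 0.993 for the KO pair, against 0.972 to 0.974 between genotypes. Libraries of a genotype differed by more than sampling noise, with a mean chi-square per gene of 46.3 for the WT pair and 37.5 for the KO pair, where sampling noise gives about 1. The fit that left out KO replicate 1 called 978 genes and the fit without KO replicate 2 called 975, against 2573 and 2231 without WT replicate 1 and WT replicate 3.

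The series title ties the study to TGF-β signalling in epithelium without Smad4, and targets of the pathway moved in both directions. Of 18 tested genes that TGF-β or BMP signals regulate through Smad4, 4 rose, 6 fell and 8 did not pass (6 rose and 8 fell when adjusted over the list alone). The transcription regulators Id3 and Id1, which BMP signals induce, fell 11.6-fold (41.9 ± 4.77 to 3.61 ± 0.760 CPM, edgeR adjusted p = 0.000591) and 2.60-fold (166 ± 6.81 to 64.0 ± 0.909 CPM, edgeR adjusted p = 0.000483). Ltbp1, which binds latent TGF-β in the matrix, rose 22.7-fold (0.325 ± 0.0600 to 7.34 ± 0.0833 CPM, edgeR adjusted p = 0.000726). Tgfbi, a matrix protein that TGF-β induces, rose 5.18-fold (3.24 ± 0.247 to 16.8 ± 0.288 CPM, edgeR adjusted p = 0.000763). As a set these targets showed no net shift against the other genes (camera adjusted p = 0.752, direction down). Their median log2 fold change was 0.08. Camera asks about a shift in 1 direction, so opposite changes cancel in it. By fry's mixed test of any change the list passed (adjusted p = 0.000740), as 27 of the 30 lists did. Of 21 ligands, receptors and other Smads, 5 rose and 2 fell (5 and 2 adjusted over the list alone). The list rose in the competitive test (camera adjusted p = 0.0348). The call was lost with an estimated correlation (camera adjusted p = 0.493), with a filter of 1 CPM (camera adjusted p = 0.0802), without WT replicate 1 (camera adjusted p = 0.103) and by fry (adjusted p = 0.0531). Between the same libraries the neutrophil marker S100a9 (mean 3.91 CPM in WT and 43.0 CPM in KO) and the fibroblast marker Fbln1 (3.13-fold) were higher in KO. Only 2 of 10 fibroblast markers rose, Fbln1 among them, and 8 did not pass. The ligand Bmp8b rose 6.03-fold (12.2 ± 3.56 to 73.2 ± 0.632 CPM, edgeR adjusted p = 0.00185), the activin subunit Inhba 6.51-fold (0.859 ± 0.306 to 5.65 ± 0.0365 CPM, edgeR adjusted p = 0.00606) and the TGF-β receptor Tgfbr2 1.66-fold (119 ± 3.92 to 198 ± 0.0919 CPM, edgeR adjusted p = 0.00213). Bmp7 rose 4.73-fold (edgeR adjusted p = 0.0220) and lost its call without WT replicate 1 and without either KO library (edgeR adjusted p up to 0.147). Tgfb1 had 9.80 ± 1.68 CPM in WT and 12.6 ± 1.54 CPM in KO and did not pass (edgeR adjusted p = 0.255), nor did Tgfb3 (edgeR adjusted p = 0.394). Tgfb2 had too few counts to be tested.

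The title also names Yap, the transcription coactivator that the Hippo pathway restrains. Yap1 itself had 88.1 ± 1.59 CPM in WT and 96.9 ± 2.95 CPM in KO (log2 fold change 0.14, SE 0.0672, edgeR adjusted p = 0.246), and its paralogue Wwtr1 (Taz) had 0.855 ± 0.237 and 1.68 ± 0.592 CPM (edgeR adjusted p = 0.232). Of 19 tested Yap/Taz-Tead target genes, 8 rose, none fell and 11 did not pass (10 rose adjusted over the list alone). The list rose in the competitive test (camera adjusted p = 0.0139), a call that was lost with an estimated correlation (camera adjusted p = 0.281). In these libraries the neutrophil marker S100a9 (mean 3.91 CPM in WT and 43.0 CPM in KO) and the macrophage marker Lyz2 (4.02-fold) were higher in KO. So were the fibroblast marker Fbln1 (3.13-fold) and the immediate early gene Ier3 (2.01-fold), though 8 of 10 fibroblast markers did not pass. Hoxb13 was 9.63-fold lower in KO, and the nuclear RNA Malat1 took 0.0709 ± 0.0147% of the counts in WT and 0.0285 ± 0.00287% in KO. The guanine nucleotide exchange factor Dock5 rose 1.47-fold (171 ± 2.60 to 252 ± 0.198 CPM, edgeR adjusted p = 0.00361). Tissue factor F3 rose 1.43-fold, Myof 1.45-fold and Amotl2 1.99-fold (8.35 ± 1.66 to 16.7 ± 1.55 CPM), with edgeR adjusted p = 0.0131, 0.0148 and 0.0223. Of the 8 risen targets, 1 kept its call in all 4 fits that left out a library. F3, Myof and Amotl2 lost theirs without either KO library (edgeR adjusted p up to 0.116, for Amotl2). Of 18 Hippo pathway components, 3 rose, none fell and 15 did not pass (4 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.365). Ptpn14 is on this list and on that of the Yap/Taz-Tead targets, so its rise counts in both. The Yap partner Tead4 rose 2.64-fold (4.74 ± 0.143 to 12.5 ± 0.0943 CPM, edgeR adjusted p = 0.00359). Wwc1 (1.43-fold, edgeR adjusted p = 0.00607) and Ptpn14 (2.04-fold, edgeR adjusted p = 0.0369) rose but lost their calls without either KO library (edgeR adjusted p up to 0.201, for Ptpn14, which also lost it without WT replicate 3). Tead3 was at 39.9 ± 1.18 and 31.0 ± 0.573 CPM and did not pass (edgeR adjusted p = 0.0542).

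Genes of the regenerating, fetal-like epithelium were higher in the KO libraries, in which the neutrophil marker S100a9 (mean 3.91 CPM in WT and 43.0 CPM in KO) was higher too. Of 18 tested, 10 rose, 1 fell and 7 did not pass (11 rose and 1 fell adjusted over the list alone). The list rose in the competitive test (camera adjusted p = 0.000161, 0.257 with an estimated correlation). The alarmin Il33 rose 10.3-fold (1.72 ± 0.331 to 17.6 ± 0.224 CPM), the urokinase receptor Plaur 4.98-fold (9.81 ± 0.0889 to 48.9 ± 0.360 CPM), Sprr1a 3.90-fold and the EGF receptor ligand Areg 2.93-fold, with edgeR adjusted p between 0.000298 and 0.000684. Genes of epithelial-mesenchymal transition and matrix proteases rose in 9 of 15 tested members and fell in none (9 adjusted over the list alone; camera adjusted p = 1.61e-06, 0.257 with an estimated correlation). The macrophage marker Lyz2 (4.02-fold) and the fibroblast marker Fbln1 (3.13-fold) were higher in the same KO libraries, though 8 of 10 fibroblast markers did not pass. The collagen-binding integrin subunit Itga2 rose 2.56-fold (92.2 ± 3.97 to 236 ± 0.910 CPM), Itgb6, whose integrin activates latent TGF-β, 2.38-fold and the gelatinase Mmp9 6.16-fold (1.13 ± 0.251 to 6.94 ± 0.0917 CPM), with edgeR adjusted p between 0.000442 and 0.00307. The collagenase Mmp13 rose 3.35-fold (edgeR adjusted p = 0.00616) and lost its call without KO replicate 2 (edgeR adjusted p = 0.0506). Of 19 Wnt target and crypt base genes, 9 rose and 1 fell (9 and 3 adjusted over the list alone), while the competitive test did not pass (camera adjusted p = 0.0922). The list passed as higher without KO replicate 1 (camera adjusted p = 0.0423), with no filter on low counts (camera adjusted p = 0.0429) and by fry (adjusted p = 0.0176). The stem cell receptor Lgr5 rose (5.19 ± 1.06 to 15.5 ± 0.352 CPM, edgeR adjusted p = 0.00547), Prom1 2.90-fold (243 ± 7.29 to 706 ± 8.46 CPM, edgeR adjusted p = 0.000209) and Cd44 2.78-fold (edgeR adjusted p = 0.000858). The ephrin receptor Ephb2 rose 1.40-fold (edgeR adjusted p = 0.00806), a call lost without either KO library (edgeR adjusted p up to 0.0823).

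Posterior Hox genes, which mark the hind end of the gut, were lower in the KO libraries. Of 8 tested, 7 fell and 1 did not pass (7 fell adjusted over the list alone), with a median log2 fold change of -4.06 (camera adjusted p = 5.06e-06, 0.257 with an estimated correlation). Hoxb13 fell 9.63-fold, from 289 ± 11.5 to 30.0 ± 1.42 CPM (edgeR adjusted p = 7.14e-05). In the Hoxd cluster, Hoxd13 fell 29.0-fold, from 110 ± 8.42 to 3.77 ± 0.860 CPM (edgeR adjusted p = 0.000258). Hoxd11 fell 54.6-fold, from 17.9 ± 0.575 to 0.318 ± 0.356 CPM (edgeR adjusted p = 0.00624), a log2 fold change of -5.77 that was -4.96 without KO replicate 1 and -8.02 without KO replicate 2. Hoxa11 and Hoxa13 fell by less, 2.62-fold and 2.09-fold (edgeR adjusted p = 0.00113 and 0.00181). All 7 kept their calls in each of the 4 fits that left out a library. The Hoxd cluster lies on chromosome 2, with Hoxd13 at 74668310 to 74671599, and Hoxb13 lies on chromosome 11 at 96194316 to 96197447 (GENCODE M21 on GRCm38). Of 19 tested Hox genes of paralogue groups 1 to 8, 9 rose, all of them in the Hoxb and Hoxd clusters, and 2 fell. The genes of these groups named here were chosen after their values were seen. Hoxb6 rose 5.84-fold (7.64 ± 0.166 to 44.7 ± 0.823 CPM, edgeR adjusted p = 0.000289) and Hoxd4 9.28-fold (2.26 ± 0.572 to 20.8 ± 0.595 CPM, edgeR adjusted p = 0.000931). The 7 tested Hoxa genes of groups 1 to 7 had log2 fold changes of -1.35 to -0.16, and Hoxa5 and Hoxa6 fell (edgeR adjusted p = 0.0463 and 0.0445). Both lost their calls without WT replicate 3 and without either KO library (edgeR adjusted p up to 0.218), and the risen Hoxb3 lost its call without KO replicate 1 (edgeR adjusted p = 0.0775).

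**Figure D2:**
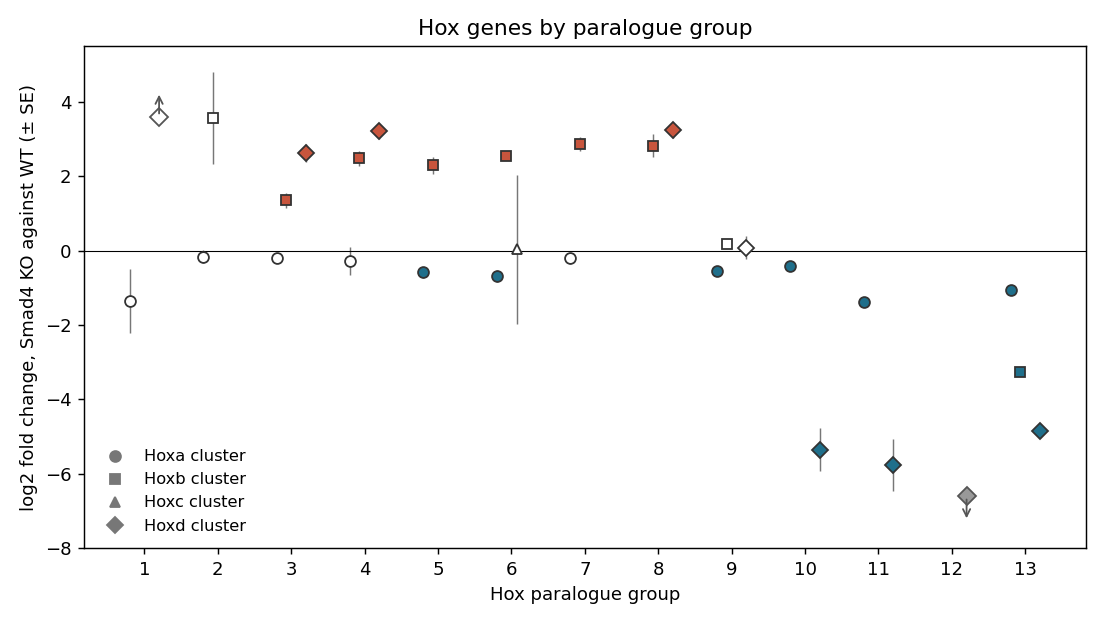
Log2 fold change of the tested Hox genes in Smad4 KO against WT (vertical axis, ± SE) by paralogue group (horizontal axis), with a marker for each cluster. Red and blue markers passed the test as higher and lower, open markers did not pass, and an arrow marks the bound for a gene at 0 in both libraries of a genotype (grey where it passed); the 8 genes of groups 10 to 13 lie below 0, and 9 of the 19 genes of groups 1 to 8 rose while Hoxa5 and Hoxa6 fell.

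Genes of differentiated epithelium changed in both directions, in libraries between which Hoxb13 differed 9.63-fold. Of 18 absorptive colonocyte genes, 10 rose, 5 fell and 3 did not pass (12 rose and 5 fell adjusted over the list alone). Carbonic anhydrase Car1 rose 2.31-fold (1131 ± 86.8 to 2607 ± 33.2 CPM, edgeR adjusted p = 0.000515) and the cytochrome P450 Cyp2c55 2.40-fold (377 ± 0.570 to 905 ± 35.1 CPM, edgeR adjusted p = 0.000298). The water channel Aqp8 fell 3.37-fold (mean 255 to 75.7 CPM, edgeR adjusted p = 0.000298) and the short-chain fatty acid transporter Slc5a8 2.42-fold (503 ± 13.4 to 208 ± 2.26 CPM, edgeR adjusted p = 0.000312). The list passed the competitive test as higher (camera adjusted p = 0.0415), but not with an estimated correlation (camera adjusted p = 0.299) nor without any of the 4 libraries in turn (camera adjusted p = 0.0620 to 0.114). Of 16 goblet cell genes, 4 rose and 6 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.394, fry adjusted p = 0.0238 as lower). Muc2, the main gel-forming mucin of the colon, rose 1.56-fold (9126 ± 259 to 14247 ± 63.7 CPM, edgeR adjusted p = 0.000515), while the mucus proteins Fcgbp (9119 ± 108 to 4595 ± 101 CPM, edgeR adjusted p = 0.000209) and Clca1 (4035 ± 68.8 to 2142 ± 61.2 CPM, edgeR adjusted p = 0.000364) fell, as did Reg4 (4.16-fold, edgeR adjusted p = 0.000289). Of 15 enteroendocrine genes, 4 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.858). The granule proteins Cpe (3.26-fold) and Chga (2.11-fold) rose, and the distal colon hormones Insl5 (3.07-fold) and Pyy (2.61-fold) fell, with edgeR adjusted p between 0.000442 and 0.00177. Of 11 tuft cell genes, 1 rose (none adjusted over the list alone). The tuft list passed the competitive test as higher (camera adjusted p = 0.0169, 0.281 with an estimated correlation, 0.118 without WT replicate 1 and 0.0585 by fry), with Rgs13 at 1.45 ± 0.239 and 2.97 ± 0.0399 CPM, Avil at 5.61 ± 0.924 and 8.59 ± 0.550 CPM and Sh2d6 at 4.11 ± 0.199 and 5.66 ± 0.587 CPM.

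General epithelial genes moved little. Of 13, 4 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.558), among them the transcription factor Cdx2 (1.50-fold higher), Epcam (1.23-fold higher), Krt18 (1.22-fold higher) and Krt19 (1.17-fold lower), with edgeR adjusted p between 0.00558 and 0.0320. These 4 calls were lost without KO replicate 2, and all but that of Cdx2 without KO replicate 1 (edgeR adjusted p up to 0.274, for Krt19), and that of Epcam also without WT replicate 1 (edgeR adjusted p = 0.0752). Of 18 tight junction and adhesion genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.116). The cadherin Cdh17 rose 1.53-fold (881 ± 9.21 to 1346 ± 8.78 CPM, edgeR adjusted p = 0.00113) and the desmosomal cadherins Dsc2 1.46-fold (edgeR adjusted p = 0.00458) and Dsg2 1.32-fold (edgeR adjusted p = 0.00705). The call of Dsg2 was lost without either KO library (edgeR adjusted p up to 0.0751). The barrier claudin Cldn8 fell 1.69-fold (157 ± 1.23 to 93.2 ± 4.10 CPM, edgeR adjusted p = 0.00246). Of 7 small-intestinal epithelial genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.614). Apob, which packages lipid into chylomicrons, rose 1.49-fold (208 ± 4.13 to 310 ± 3.24 CPM, edgeR adjusted p = 0.00307). The ileal bile acid binding protein Fabp6 fell (4.31 ± 1.36 to 0.719 ± 0.254 CPM, edgeR adjusted p = 0.0148) and lost its call without KO replicate 2 (edgeR adjusted p = 0.0693).

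Epithelial antimicrobial and inflammatory genes were higher in the KO libraries, where the neutrophil marker S100a9 (mean 3.91 CPM in WT and 43.0 CPM in KO) was higher too. Of 16 antimicrobial genes, 8 rose, 3 fell and 5 did not pass (8 and 3 adjusted over the list alone). The antibacterial lectins Reg3b and Reg3g rose 7.72-fold (732 ± 44.2 to 5655 ± 145 CPM) and 7.31-fold (241 ± 9.77 to 1763 ± 73.2 CPM), and the inducible nitric oxide synthase Nos2 rose 7.65-fold (87.6 ± 2.67 to 670 ± 9.66 CPM), each with edgeR adjusted p = 4.92e-05. The hydrogen peroxide-producing oxidase Duox2 rose 2.54-fold (623 ± 5.10 to 1579 ± 26.0 CPM, edgeR adjusted p = 0.000197). The list passed the competitive test (camera adjusted p = 0.0254), but not with an estimated correlation (camera adjusted p = 0.531), on ranks (camera adjusted p = 0.132), without WT replicate 3 (camera adjusted p = 0.0973) or without KO replicate 2 (camera adjusted p = 0.0874). Of 23 cytokine and chemokine genes, 14 rose, 2 fell and 7 did not pass (17 and 3 adjusted over the list alone; camera adjusted p = 5.01e-06, 0.257 with an estimated correlation). Besides Cxcl5, Il1b rose 4.74-fold (12.4 ± 0.815 to 58.6 ± 0.444 CPM, edgeR adjusted p = 0.000364), Tnf (6.34 ± 0.365 to 25.4 ± 0.877 CPM, edgeR adjusted p = 0.000719) and Cxcl2 5.04-fold (4.57 ± 0.663 to 23.1 ± 1.12 CPM, edgeR adjusted p = 0.000942). Of 22 genes of the interferon response and antigen presentation, 9 rose and 5 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.134, fry adjusted p = 0.0435 as higher). The interferon-induced GTPase Gbp2 rose 3.36-fold (136 ± 4.40 to 457 ± 6.70 CPM, edgeR adjusted p = 0.000197) and the chemokine Cxcl10 3.56-fold (edgeR adjusted p = 0.00150). The MHC class II invariant chain Cd74 fell 3.96-fold (417 ± 9.82 to 105 ± 2.50 CPM, edgeR adjusted p = 0.000197) and the class II chain H2-Aa 3.72-fold (71.9 ± 1.81 to 19.3 ± 2.47 CPM, edgeR adjusted p = 0.000786).

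**Figure D3:**
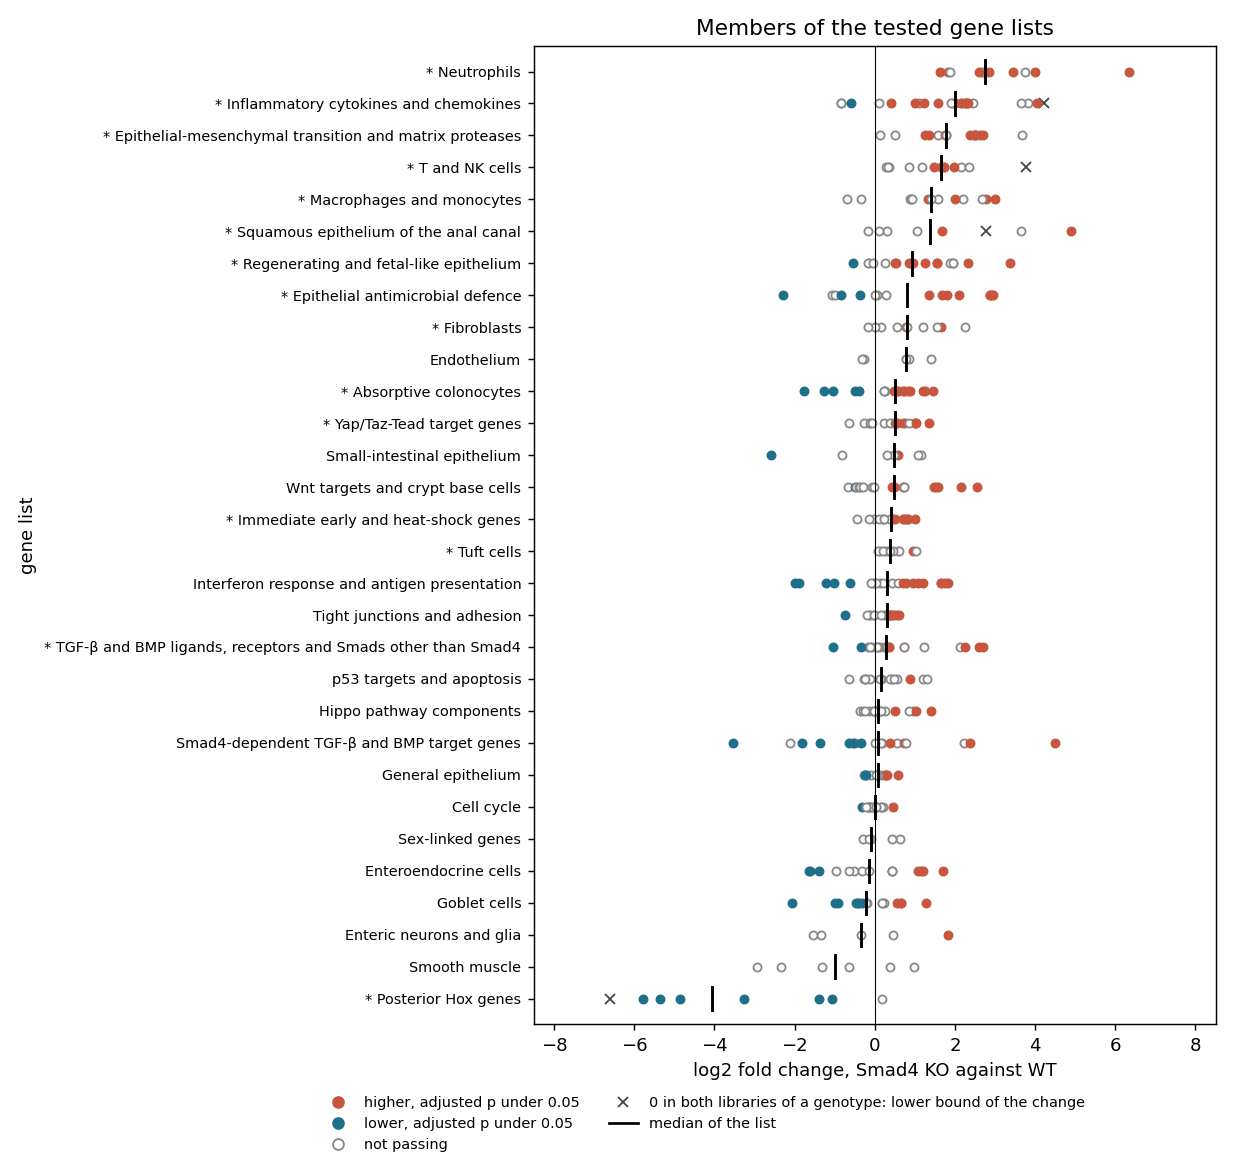
Log2 fold change in Smad4 KO against WT (horizontal axis) of each tested member of the 30 gene lists with at least 5 tested members (vertical axis, sorted by median). Filled points passed the gene test as higher (red) or lower (blue), open points did not, crosses mark lower bounds, black bars are list medians and an asterisk marks the 15 lists with camera adjusted p under 0.05; neutrophil markers have the highest median, 2.75, and posterior Hox genes the lowest, -4.06.

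Markers of other cell types were mostly at low levels, and several of these lists were higher in KO. Of the tested immune, stromal and neural markers, Ly6g, Cd14 and Fbln1 had 10 CPM or more in WT. Of 11 neutrophil markers, 8 rose and none fell (10 adjusted over the list alone; camera adjusted p = 2.57e-06, 0.257 with an estimated correlation). The calprotectin subunits S100a8 and S100a9 rose from 2.72 ± 1.41 to 43.7 ± 0.497 CPM (15.9-fold, edgeR adjusted p = 0.00246) and from 3.91 ± 0.758 to 43.0 ± 0.488 CPM (edgeR adjusted p = 0.000434), while the colony-stimulating factor receptor Csf3r rose 3.56-fold (edgeR adjusted p = 0.00241). The log2 fold change of S100a8 was 3.99, and 4.65 without WT replicate 1. The most abundant listed marker, Ly6g, rose from 105 ± 16.2 to 324 ± 7.53 CPM (edgeR adjusted p = 0.00123) and so stood far above S100a8 in WT; it belongs to a family of similar genes, as does Ly6c2, and its value is uncertain. Of 13 macrophage and monocyte markers, 4 rose and none fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.00867, 0.281 with an estimated correlation). Lyz2 rose 4.02-fold (4.67 ± 1.28 to 18.8 ± 0.0969 CPM, edgeR adjusted p = 0.00420) and Ly6c2 6.85-fold (edgeR adjusted p = 0.00728). Itgam (7.93-fold, edgeR adjusted p = 0.0117) and Csf1r (2.52-fold, edgeR adjusted p = 0.0131) rose but lost their calls without KO replicate 1 (edgeR adjusted p = 0.0512 and 0.0860). The log2 fold change of Itgam was 2.99, and 3.84 without WT replicate 1. Cd14, at 170 ± 15.5 and 135 ± 2.04 CPM, did not pass (edgeR adjusted p = 0.0550). Of 13 T and NK cell markers, 5 rose (5 adjusted over the list alone; camera adjusted p = 8.23e-05, 0.257 with an estimated correlation), among them the granzymes Gzma (2.78-fold) and Gzmb (3.93-fold, 1.58 ± 0.327 to 6.25 ± 1.48 CPM), Cd7 (3.13-fold) and Cd4, which had no count in WT and 0.409 ± 0.0145 CPM in KO and was at least 13.7-fold higher. None of these 5 kept its call in all 4 fits that left out a library, with edgeR adjusted p up to 0.249 for Cd4. Gzma and Cd7 lost theirs without either KO library, Gzmb without KO replicate 2 and Cd4 without any of the 4 libraries in turn. Itgae, the marker of this list with the highest level, was at 3.89 ± 1.45 and 4.90 ± 0.316 CPM and did not pass (edgeR adjusted p = 0.543).

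Of 10 fibroblast markers, 2 rose (2 adjusted over the list alone; camera adjusted p = 0.0242, 0.285 with an estimated correlation, 0.0620 with a filter of 1 CPM, 0.0698 without WT replicate 1 and 0.0670 without KO replicate 2). Fbln1 rose 3.13-fold (10.0 ± 0.400 to 31.4 ± 4.67 CPM, edgeR adjusted p = 0.00222). Dcn rose 1.72-fold (edgeR adjusted p = 0.0357), a call lost without WT replicate 3 and without either KO library (edgeR adjusted p up to 0.200). Col1a2 was at 1.29 ± 0.507 and 2.95 ± 0.819 CPM and did not pass (edgeR adjusted p = 0.123). None of 6 smooth muscle and none of 6 endothelial markers passed (none adjusted over the lists alone, camera adjusted p = 0.256 and 0.428). The smooth muscle markers had a median log2 fold change of -0.98, and 2 of the 6 were positive. Tagln was at 1.52 ± 0.113 and 3.03 ± 1.27 CPM and Synpo2 at 2.94 ± 0.585 and 1.17 ± 0.360 CPM. The endothelial markers had a median of 0.78, with Vwf at 5.17 ± 0.960 and 4.28 ± 0.939 CPM. Of 5 markers of enteric neurons and glia, Ret rose (3.54-fold, edgeR adjusted p = 0.00112; 1 adjusted over the list alone; camera adjusted p = 0.798 with the direction down, fry adjusted p = 0.0305 with the direction up). Of 8 squamous markers of the anal canal, 2 rose (3 adjusted over the list alone; camera adjusted p = 0.0114, 0.281 with an estimated correlation and 0.128 without KO replicate 2). These were the desmoglein Dsg3 (0.183 ± 0.260 to 5.13 ± 0.656 CPM, edgeR adjusted p = 0.0397) and the keratin Krt13 (0.522 ± 0.0402 to 1.67 ± 0.112 CPM, edgeR adjusted p = 0.0477), and both lost their calls without either KO library (edgeR adjusted p up to 0.265), Krt13 also without either WT library. Dsg3 also lost its call with DESeq2's Wald test (adjusted p = 0.152) and edgeR's robust fit, and Krt13 with library totals and limma-voom. The log2 fold change of Dsg3 was 4.90, and 3.78 without WT replicate 1, which had no count of it. Without WT replicate 3 no count was left in WT, and Dsg3 was at least 96.9-fold higher in KO (floor of 3 counts). The 4 tested B and plasma cell markers and the 4 of red blood cells were too few for the competitive test. Igha, at a mean of 2.30 CPM in WT, did not pass (edgeR adjusted p = 0.115). Hba-a1 rose from 0.372 ± 0.0722 to 3.37 ± 0.667 CPM (edgeR adjusted p = 0.00561), a call lost without KO replicate 2 (edgeR adjusted p = 0.0516) and uncertain because near-identical globin genes share reads. None of the 9 listed pancreatic genes had enough counts to be tested. All 4 libraries expressed Y-linked genes, with Kdm5d at 62.7 ± 0.567 and 56.9 ± 0.821 CPM. None of 5 sex-linked genes passed (camera adjusted p = 0.610).

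Of 20 cell cycle genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.670). The proliferation marker Mki67 fell 1.25-fold (346 ± 9.65 to 277 ± 2.42 CPM, edgeR adjusted p = 0.0189) and the ribonucleotide reductase subunit Rrm2 rose 1.36-fold (edgeR adjusted p = 0.0261), and both lost their calls without either KO library (edgeR adjusted p up to 0.187), Rrm2 also without WT replicate 1. Of 15 p53 target and apoptosis genes, 2 rose (3 adjusted over the list alone; camera adjusted p = 0.141, fry adjusted p = 0.00448 as higher). These were Bcl2l11 (1.83-fold, edgeR adjusted p = 0.0267) and Mdm2 (1.34-fold, edgeR adjusted p = 0.0273), with both calls lost without either KO library (edgeR adjusted p up to 0.180) and that of Mdm2 also without WT replicate 3. Immediate early and heat-shock genes, which also respond to tissue handling, rose in 8 of 16 members and fell in none (11 rose adjusted over the list alone; camera adjusted p = 0.00120, 0.257 with an estimated correlation). The chaperone Hspa8 rose 1.43-fold (739 ± 0.683 to 1054 ± 30.0 CPM, edgeR adjusted p = 0.00261) and Ier3 2.01-fold (edgeR adjusted p = 0.00527). Atf3 (1.76-fold, edgeR adjusted p = 0.00721) and Egr1 (1.74-fold, edgeR adjusted p = 0.0103) rose and lost their calls without KO replicate 1 (edgeR adjusted p = 0.0528 and 0.0608), Egr1 also without KO replicate 2 (edgeR adjusted p = 0.0660). Mitochondrial genes took 4.34 ± 0.249% of the counts in WT and 5.31 ± 0.124% in KO, and the nuclear RNA Malat1 took 0.0709 ± 0.0147% and 0.0285 ± 0.00287%.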

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

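The alternatives were chosen before the data were examined except the 2 said to be added. Smad4 stayed lower and past the threshold in all 15 alternatives, with a log2 fold change of -2.01 to -1.69 and adjusted p up to 0.00868. The count of changed genes fell from 2412 (1398 higher, 1014 lower) to 1101 (697 higher, 404 lower) when at least 2-fold change was required, which by construction removes smaller changes, and DESeq2's Wald test called 1524 lower genes (3446 in all), for which the cause was not tested. Leaving out 1 library gave 975 to 2573 changed genes, 547 to 1504 higher and 425 to 1069 lower; the low ends came from the fits without KO replicate 1 (978) or KO replicate 2 (975), in which the lone KO library was assumed to vary like the WT pair. Of the 2412 genes, 907 and 917 were called again in these 2 fits, and all 2412 were tested there and had the same sign. The shared sign is no separate support, because the 2412 genes were chosen on the same libraries. With library totals in place of TMM the genes split into 1232 higher and 1211 lower, 50.4% higher against 58.0%. Of 2 alternatives added after seeing the data, summing rows that share a symbol gave 2420 genes and leaving out calls at 0 in both libraries of a genotype gave 2328. The number of lists passing the competitive test went from 15 to 0 with an estimated correlation, the cause not tested beyond the few residuals behind that estimate, and lay between 12 and 15 when 1 library was left out, 1 of them red blood cells, testable only there, in 3 of these 4 fits; of the 30 lists, 11 to 15 passed, with 11 without WT replicate 1 and 11 without KO replicate 2. A higher correlation cannot have removed the calls of lists whose estimate was below the preset 0.01, such as neutrophil markers (-0.0862). The test with an estimated correlation itself rests on few residuals. Since all 15 lists lost their calls under it, that loss does not tell the lists apart. The enteric neuron and glia list turned from down (not passing) to up and passing with fry (adjusted p = 0.0305, range over its alternatives 0.0305 to 0.947). The fry test does not compare the list with other genes. The gap between the lowest r within a genotype and the highest r between genotypes, 0.0175, was 0.0160 with log2(CPM + 5) and 0.359 over the 500 most variable genes, which were selected for varying. Of the 151 other named genes none changed sign with a call, 31 of the 109 called lost it in a fit without some library and 7 under another setting. Genes left out by a filter or among the 20 most abundant have no value there, and 1 CPM in 2 libraries left 5 lists with too few genes. No paired analysis was possible because the groups share only 1 replicate number. Depth limits genes near the floor of 0.0299 CPM for WT and 0.0237 CPM for KO, and in the simulated comparison with 2400 changed genes (about 15390 tested) 34.9% of 1.5-fold changes were recovered.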

Other observations

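Among abundant genes outside the lists, chosen after their values were seen as those with the largest gain or loss of CPM, several epithelial genes moved. The adhesion molecule Ceacam1 rose 1.77-fold (3624 ± 196 to 6409 ± 23.4 CPM, edgeR adjusted p = 0.000682), Clca4b 5.10-fold (482 ± 16.4 to 2459 ± 10.6 CPM, edgeR adjusted p = 4.92e-05), the placenta-expressed surface protein Plet1 6.04-fold (132 ± 2.64 to 794 ± 3.24 CPM, edgeR adjusted p = 4.92e-05) and transglutaminase Tgm2 6.81-fold (120 ± 6.27 to 816 ± 37.3 CPM, edgeR adjusted p = 9.03e-05). Emp1 rose 6.39-fold (136 ± 92.4 to 871 ± 22.7 CPM, edgeR adjusted p = 0.0220) but was called in 2 of the 4 fits that left out a library. The log2 fold change of Emp1 was 2.68, 2.1 without WT replicate 1 and 3.62 without WT replicate 3. The stearoyl-CoA desaturase Scd2 fell 3.09-fold (2143 ± 127 to 695 ± 5.35 CPM, edgeR adjusted p = 0.000209), another transglutaminase, Tgm3, 8.95-fold (1306 ± 24.1 to 146 ± 7.39 CPM, edgeR adjusted p = 4.92e-05), alcohol dehydrogenase Adh1 5.28-fold (edgeR adjusted p = 5.82e-05) and the gasdermin Gsdmc4 3.21-fold (edgeR adjusted p = 0.000209).

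The fixed list of the interferon response and antigen presentation did not pass the competitive test (camera adjusted p = 0.134; fry adjusted p = 0.0435). Outside it, 4 genes that interferons can induce were picked after their values were seen, and they stand for no group. The tryptophan-degrading enzyme Ido1 rose 8.88-fold (52.0 ± 1.21 to 461 ± 2.62 CPM, edgeR adjusted p = 4.92e-05), the checkpoint ligand Cd274 (PD-L1) 8.97-fold (12.1 ± 1.20 to 109 ± 1.58 CPM, edgeR adjusted p = 0.000197) and the GTPases Gbp4 and Gbp5 7.85-fold and 7.93-fold (edgeR adjusted p = 0.000393 and 0.000221).

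Of the tests below, 3 were chosen after the result they measure was seen: the one on stromal markers, the one on Smad4 loss and Hox genes, and the comparison of neutrophil with stromal markers. The test of overlap on either strand was written before its own result but after that for the same strand. Of the 8 tested posterior Hox genes, 7 fell in KO (camera adjusted p = 5.06e-06 for the list, 0.257 with an estimated correlation). This list holds Hoxb9, which did not pass, and not Hoxa10, both named after their values were seen. The 8 tested genes of paralogue groups 10 to 13 include Hoxa10 and not Hoxb9, and all 8 fell, Hoxa10 by 1.34-fold (edgeR adjusted p = 0.0176). Fewer stromal cells would lower stromal markers by about as much. The 22 tested markers of fibroblasts, smooth muscle and endothelium instead had a median log2 fold change of 0.67 (quartiles -0.25 and 0.95). By cell type the medians were 0.80 for 10 fibroblast, 0.78 for 6 endothelial and -0.98 for 6 smooth muscle markers. The pooled median therefore does not speak for smooth muscle. A more proximal stretch of colon in the KO libraries predicts that Hox genes of paralogue groups 1 to 8 do not fall along with groups 10 to 13. Their median was 2.29 over 19 genes, 9 of them risen (all in the Hoxb and Hoxd clusters) and 2 fallen (Hoxa5 and Hoxa6, both lost without either KO library, edgeR adjusted p up to 0.218), against -4.06 over the 8 genes of groups 10 to 13, so this explanation stays open for part or all of the genotype difference, although 2 of 8 squamous anal markers rose in KO. Both of these calls were lost without either KO library, and that of the list with an estimated correlation (camera adjusted p = 0.281) and without KO replicate 2 (camera adjusted p = 0.128). An effect of Smad4 loss on Hox genes cannot be told apart from it, because both KO libraries lie below both WT libraries (by 2.31 in the median log2(CPM + 1) of the posterior Hox list) and no library separates genotype from position.

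Of 16 antimicrobial genes 8 rose and 3 fell, and of 23 cytokine and chemokine genes 14 rose and 2 fell, beside 8 risen of 11 neutrophil markers. With an estimated correlation none of these 3 lists passed (camera adjusted p = 0.531, 0.257 and 0.257), and the antimicrobial list also lost its call on ranks (camera adjusted p = 0.132), without WT replicate 3 (camera adjusted p = 0.0973) and without KO replicate 2 (camera adjusted p = 0.0874). A lower share of epithelium as the only change would raise all other cell types alike. Neutrophil markers (median log2 fold change 2.75, 11 genes) instead rose by more than stromal markers (0.67, 22 genes). The 2-sided permutation p was 2e-05 over genes, which are not independent. The stromal markers were themselves mixed, with medians of 0.80 for fibroblasts and -0.98 for smooth muscle. The test cannot exclude a lower share of epithelium together with more neutrophils. Neutrophil RNA as the source is argued against for 5 of the 8 risen antimicrobial genes (62.5%). These gained more CPM than the abundant neutrophil transcripts S100a8 and S100a9 together (80.1 CPM), with gains from 227 CPM to 4923 CPM (Reg3b). The listed neutrophil marker Ly6g, whose value is uncertain, went from 105 to 324 CPM and so gained more than that pair. Lcn2 (4.03 CPM), Saa3 (12.4 CPM) and Slpi (51.1 CPM) gained less, so their source stays open. None of the 14 risen cytokine and chemokine genes gained more than 80.1 CPM (0%). This cannot decide their source, because nearly all of them stood below that level in KO. Il1b, at 58.6 CPM, was the highest in KO after Ccl6, which went from 239 to 316 CPM. Whether RNA from neutrophils contributed to these genes stays open, and the design cannot separate that from expression by the epithelium. The genotype itself stays open for the antimicrobial genes, as does the position along the colon.

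Of the changed genes, 84 had no count in either library of a genotype, 54 of them in WT and 30 in KO, at a median of 0.346 CPM over all libraries. Reads assigned to an overlapping gene model would leave most of them with little change in the sum. On the same strand 12 genes overlap a model, and 7 of the 84 (8.33%), Sept2 among them, changed by less than 2-fold when summed with it. On either strand 31 overlap a model, and 15 (17.9%) changed by less than 2-fold when summed, an upper limit because an abundant model hides a change, so this stays open for up to 15 of them. A passenger segment around Smad4 on chromosome 18 could account for most of the set only by holding many of them, and 1 lies within 10 Mb of Smad4. For that gene such a segment stays open, and changed genes outside the set were not part of this test. Larger strain segments elsewhere, if they held most of the set, would bring neighbours together. Of the 84 genes, 14 have another of the set within 1 Mb, where 95% of 10000 random sets of tested genes had 4 to 20. This count cannot exclude segments that hold few of these genes or hold them further apart. Single strain variants and regulation of weakly expressed genes were not tested and stay open.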
